A study of Mus musculus with 16 samples.

How the data were processed

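RNA was measured by sequencing in 16 libraries of mouse bone marrow-derived macrophages. Marrow was cultured for some days in medium with L929-conditioned supernatant and then treated for 24 h with 100 nM dexamethasone or with vehicle, per the labels' protocols. The groups were wild type and Foxo3 knockout, each with vehicle and with dexamethasone, with 4 libraries per group. Group and replicate number were taken from the sample labels. RNA was extracted with TRIzol and sequenced on an Illumina instrument, per the labels' protocols.

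The authors deposited 1 table of FPKM values per library, with 54532 Ensembl gene identifiers in each. Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq2 are named, with the builds GRCm38 and mm10, per the submitters' processing notes. The role of each tool, the strand setting of the counting and the annotation version are not given in the sources used here. Gene names, positions and exon lengths came from GENCODE M21 on GRCm38, which held 54495 of the identifiers; the other 37 carried at most 0.00529% of the FPKM of a library and were left out where a name was needed. Without a known strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart.

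FPKM is not a count, so no count model was the main test. In 88.6% of 5637 low genes the smallest positive value matched, within 0.1%, what a single read is worth at the gene's exon length. On that basis 96.5% of the positive values came out whole within 0.05 reads. The recovered reads on genes lay between 16886746 and 20584579 per library. They stood at 0.982 to 1.24 times the denominators behind the FPKM values, so the denominators were not the sums of these reads. No pair of libraries differed by as little as sampling noise would give, and each was counted as its own replicate. Median-ratio factors computed from the FPKM ranged from 0.954 to 1.06.

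Values were tested as log2(FPKM + 1), with the pseudocount of 1 FPKM, which understates changes of low genes. Genes with at least 1 FPKM in at least 4 of the 16 libraries were kept, which left 11654. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (intensity trend, moderated variance), and p-values were two-sided and adjusted by Benjamini-Hochberg within each of 5 comparisons, with a threshold of 0.05. These were dexamethasone against vehicle in each genotype, knockout against wild type in each treatment, and the difference between both responses (interaction). Foxo3 itself was compared by an exact permutation test on FPKM. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

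Before the data were examined, 31 gene lists covering pathways, other cell types and RNA quality were fixed. Of these, 25 had at least 3 measured members and were tested with camera from limma at a preset correlation of 0.01, adjusted over the 25 lists of each comparison. Camera was run again with the correlation estimated per list, and 6 of the 44 list calls then passed: receptor targets in both genotypes, FOXO targets in wild type with dexamethasone and in both genotype comparisons, and interferon genes in wild type. Counts of members are given over all genes tested and adjusted over the list alone. The lists on iron handling and the circadian clock were written after the data were seen.

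The genes named were chosen by a rule written before the data were examined. It covers Foxo3 and related genes, the genes with the steepest change in each direction among those past the threshold with no overlap between groups, up to 4 called members of each list with the smallest adjusted p, and the first 3 measured members of each list. It skips unnamed identifiers and predicted genes among the steepest. Genes outside it are said to have been chosen after their values were seen. Some genes that the rule covers are not reported here.

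The steps were tested on simulated data with the real spread of each gene, in which 100 genes each were shifted by 1 and by 2 on the log2 scale. Of those shifted by 1, the dexamethasone comparisons recovered 88 in wild type and 90 in knockout, the genotype comparisons 90 in vehicle and 81 under dexamethasone, and the interaction 77. Of those shifted by 2, these steps recovered 99, 97, 96, 95 and 89. Unshifted genes made up 7%, 5.1%, 4.1%, 3.8% and 5.1% of the calls, at the threshold of 0.05. The simulated genes varied independently of each other, whereas in the real libraries many genes, such as stromal ones, vary together. The simulation therefore does not give the share of false calls in these data.

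Alternatives were another pseudocount, filter, scaling, weighting, set of groups in the fit and replicate block, and each library left out in turn. After the data were seen, 4 more were added: a stromal marker score as a covariate, 3 libraries left out that lay apart in Col1a1, only libraries with Col1a1 under 50 FPKM, and limma voom on the recovered reads.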

Results

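The deposited data were RNA-sequencing expression values from 16 libraries of mouse bone marrow-derived macrophages, cells grown from marrow in medium conditioned by L929 fibroblasts, which supplies macrophage growth factor. The libraries formed 4 groups of 4. Wild-type cells and cells labelled Foxo3 knockout each received vehicle (DMSO) or 100 nM dexamethasone, a synthetic agonist of the glucocorticoid receptor, for 24 h. Per the series title, the study asked how FOXO3, a forkhead transcription factor, bears on signalling by the glucocorticoid receptor. Values were FPKM (fragments per kilobase of exon, scaled to depth). The reads on genes recovered from them came to between 16886746 and 20584579 per library. By the denominators behind the FPKM values, a 2 kb gene at 1 FPKM rested on 32.9 to 39.7 reads. After a filter on low values, 11654 genes were tested. The labels number the replicates without saying whether they came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

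No difference between the genotypes was detected in the targeted gene. Foxo3 (ENSMUSG00000048756) lies on the minus strand of chromosome 10 at 42181841 to 42276755 (GRCm38), and its value covers all annotated exons. It stood at 24.7 ± 1.72 FPKM in wild-type vehicle libraries (SD, n = 4) and at 23.8 ± 0.635 FPKM in knockout-labelled vehicle libraries, a two-sided exact permutation p of 0.371. Under dexamethasone the levels were 23.2 ± 1.07 and 24.5 ± 1.44 FPKM, with an exact permutation p of 0.171; the smallest p that 70 splits allow is 0.0286. The part of the gene removed in the knockout is not given in the sources used here. A whole-gene value need not fall when part of a transcript is lost, so it did not check the genotype labels, and every genotype direction given here rests on the labels. The receptor gene Nr3c1 gave log2 differences with dexamethasone of -0.30 ± 0.12 (SE) in wild type and -0.30 ± 0.12 in knockout, neither of which passed (limma adjusted p = 0.0802 and 0.069). Foxo1, a related forkhead factor, rose with dexamethasone in both genotypes, from 2.28 ± 0.152 to 3.01 ± 0.07 FPKM in wild type and from 2.27 ± 0.142 to 2.81 ± 0.1 FPKM in knockout (limma adjusted p = 0.00124 and 0.00572).

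**Figure D1:**
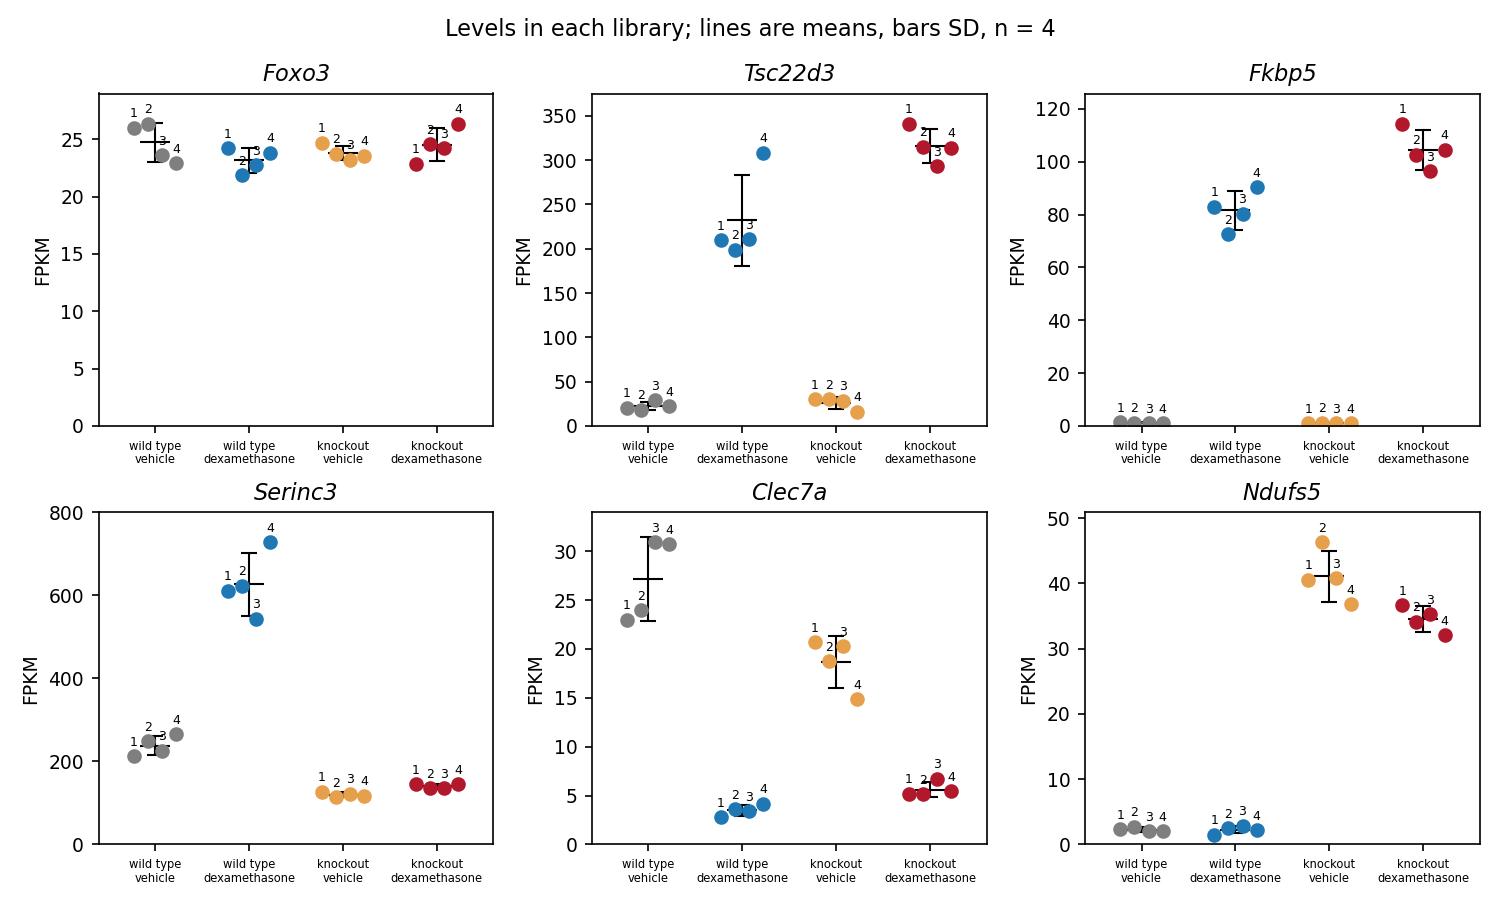
FPKM of Foxo3, Tsc22d3, Fkbp5, Serinc3, Clec7a and Ndufs5 in each library, by group; points are libraries with their replicate number, horizontal lines are group means and bars are SD (n = 4), on linear axes from 0. Foxo3 lies between 21.9 and 26.4 FPKM in all 16 libraries, while Fkbp5 stands near 1 FPKM in both vehicle groups.

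Transcripts of fibroblasts and other stromal cells differed between libraries within groups as well as between groups. Col1a1, a collagen chain made by fibroblasts, measured 127, 124 and 174 FPKM in wild-type vehicle replicates 1, 2 and 4 and 6.77 FPKM in replicate 3. In wild-type dexamethasone libraries it measured 355.5, 159 and 286 FPKM in replicates 1 to 3 and 19.1 FPKM in replicate 4. Knockout-labelled vehicle replicates 1 to 3 held 4.76, 0.506 and 0.395 FPKM, and replicate 4 held 95.8 FPKM. In knockout-labelled dexamethasone libraries Col1a1 lay between 1.18 and 25.5 FPKM. The mean log2(FPKM + 1) of 10 stromal marker genes ranked the libraries in a similar way, from 0.35 to 5.88. Knockout minus wild type, the median difference of these markers was -2.30 on the log2 scale in vehicle and -3.11 under dexamethasone. The comparisons between genotypes that follow all carry this difference.

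**Figure D2:**
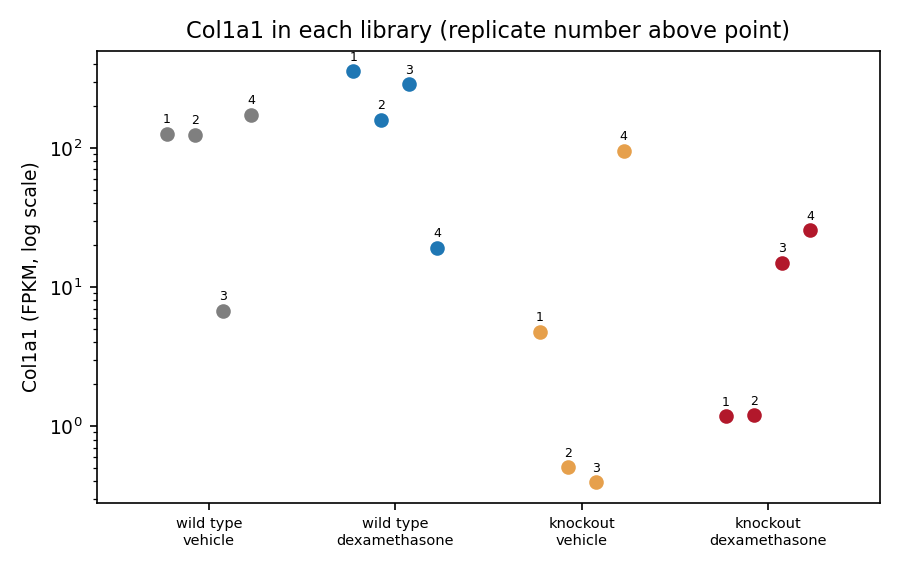
Col1a1 in each of the 16 libraries, in FPKM on a log axis, by group; numbers above the points are replicate numbers. In each of 3 groups 1 library lies apart from the other 3, at 6.77, 19.1 and 95.8 FPKM.

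In wild-type macrophages dexamethasone raised the glucocorticoid receptor targets Fkbp5 and Tsc22d3, while the interferon-induced gene Ifit3, the class II genes H2-Ab1 and Cd74 and the cytokine gene Tnf fell. Fkbp5, a co-chaperone of the receptor, rose from 1.19 ± 0.185 to 81.6 ± 7.28 FPKM (SD, n = 4), 5.24 ± 0.076 (SE) on the log2(FPKM + 1) scale (limma, Benjamini-Hochberg adjusted p = 1.49e-15). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 22.6 ± 4.79 to 232 ± 51.2 FPKM. The steepest rises among genes that separated the groups in every library included Jaml, an adhesion molecule (5.23 ± 0.27), Sult1a1, a sulfotransferase (3.88 ± 0.17), F13a1, a subunit of coagulation factor XIII (3.83 ± 0.23), and Ms4a4a, a membrane protein of macrophages (3.69 ± 0.25). The steepest falls included Cd72, a lectin-like receptor, which fell from 19.5 ± 4.57 to 0.758 ± 0.506 FPKM, and Mmp12, macrophage elastase, from 129.9 ± 53 to 12.7 ± 3.7 FPKM. In all, 3508 of 11654 genes passed at an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1386 higher and 2122 lower, and 511 of them changed by at least 1 on the log2 scale.

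Of 22 measured glucocorticoid receptor targets, 14 rose and 2 fell in wild type, or 17 and 3 when adjusted over the list alone (camera adjusted p = 3.23e-10, and adjusted p = 0.00408 with an estimated correlation). The clock gene Per1 and the transcription factors Klf9 and Zbtb16 rose by 2.55 ± 0.11, 2.40 ± 0.13 and 2.69 ± 0.11 (log2, SE, limma adjusted p = 2.7e-09, 1.06e-08 and 1.43e-09). Ddit4, an inhibitor of mTORC1 signalling, rose from 10.4 ± 6.47 to 213 ± 33.6 FPKM. FOXO target genes leaned the same way, with 15 of 27 higher and 3 lower (18 and 3 adjusted over the list alone; camera adjusted p = 1.85e-05, and adjusted p = 0.0186 with an estimated correlation). Among them Cited2, Pik3r1 and Cdkn1b, a cell cycle inhibitor, rose by 1.36 ± 0.10, 0.79 ± 0.08 and 0.68 ± 0.08, while Bcl6, a repressor of transcription, fell from 10.1 ± 1.85 to 5.92 ± 0.584 FPKM. Interferon-response genes fell in 26 of 29 cases (27 adjusted over the list alone; camera adjusted p = 1.09e-18, and adjusted p = 0.0186 with an estimated correlation). Ifit3, an antiviral effector, fell from 12 ± 1.59 to 0.986 ± 0.343 FPKM, and Irf7, a transcription factor of the same response, from 14.8 ± 2.59 to 4.7 ± 1.42 FPKM.

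Genes of antigen presentation by MHC class II fell in 8 of 10 cases, both overall and adjusted over the list alone, with camera adjusted p = 3.44e-06, and adjusted p = 0.175 with an estimated correlation. H2-Ab1, a class II chain, fell from 31.6 ± 12.1 to 2.68 ± 0.753 FPKM, Cd74, the invariant chain, from 575 ± 178 to 73.8 ± 22.2 FPKM, and Ciita, the class II transactivator, from 2.34 ± 0.962 to 0.105 ± 0.095 FPKM. NF-kB inflammatory genes fell in 11 of 21 cases and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000256, and adjusted p = 0.0948 with an estimated correlation). Tnf fell from 6.37 ± 0.929 to 0.705 ± 0.147 FPKM and Icam1, an adhesion molecule, from 23.4 ± 2.19 to 8.52 ± 2.24 FPKM, whereas the chemokine Ccl2 stood at 26.7 and 19.3 FPKM and did not pass (limma adjusted p = 0.514). Fc receptor, complement and phagocytic genes fell in 14 of 24 cases and rose in 3, and the counts adjusted over the list alone were equal (camera adjusted p = 0.000248, and adjusted p = 0.381 with an estimated correlation). The activating receptors Fcgr1 and Fcgr4 fell by 2.76 ± 0.17 and 1.46 ± 0.13 (log2, SE; limma adjusted p = 3.65e-08 and 1.73e-06). Cell cycle genes fell in 17 of 29 cases (24 adjusted over the list alone; camera adjusted p = 1.65e-07, and adjusted p = 0.604 with an estimated correlation). Mcm5, a replication helicase subunit, fell from 10.6 ± 2.81 to 3.49 ± 0.914 FPKM. The proliferation marker Mki67 stood at 3.91 and 2.08 FPKM and did not pass (limma adjusted p = 0.119). Genes of cholesterol synthesis fell in 8 of 20 cases, with an equal count adjusted over the list alone (camera adjusted p = 0.00682, and adjusted p = 0.687 with an estimated correlation). The regulator Srebf2 fell from 29.2 ± 4.38 to 14.2 ± 1.31 FPKM.

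Genes associated with glucocorticoid-treated, apoptotic cell-clearing macrophages went both ways in wild type, 7 higher and 7 lower of 21 (7 and 8 adjusted over the list alone; camera adjusted p = 0.739). The median was 0.02, the mean -0.056 and the direction of the test higher. Cd163, the haemoglobin scavenger receptor, rose from 2.16 ± 0.315 to 10.2 ± 1.52 FPKM, and Mertk, a receptor for apoptotic cells, from 32.8 ± 2.29 to 101 ± 24.3 FPKM. Stromal markers did not pass between these groups (camera adjusted p = 0.342). Macrophage markers fell in 7 of 10 cases and rose in 2, with equal counts adjusted over the list alone. Their list did not pass (camera adjusted p = 0.207), but passed as lower without the 3 libraries apart in Col1a1 (camera adjusted p = 0.0418). Among them Adgre1, which encodes F4/80, fell from 615 ± 118 to 279.7 ± 128 FPKM. Median-ratio scaling gave 3595 calls, 48.4% of them higher against 39.5% with the deposited scaling, so the excess of lower over higher genes depends on the scaling. Among the 9 libraries under 50 FPKM of Col1a1, with 1 wild-type library per treatment assumed to vary like the other groups, 2155 genes passed.

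In knockout-labelled macrophages the receptor targets Fkbp5, Tsc22d3 and Ddit4 rose with dexamethasone, and the interferon-induced gene Ifit2 and the chemokine gene Ccl3 fell. Fkbp5 rose from 1.03 ± 0.0857 to 104 ± 7.46 FPKM (SD, n = 4), a difference of 5.70 ± 0.076 (SE, log2; limma, Benjamini-Hochberg adjusted p = 4.39e-16). Tsc22d3 rose from 26.3 ± 6.69 to 316 ± 19.6 FPKM, Ddit4 from 4.04 ± 3.71 to 339.9 ± 28 FPKM and Sult1a1 from 7.05 ± 1.14 to 183 ± 27 FPKM. Saa3, an acute-phase protein made by macrophages, rose from 8.49 ± 3.05 to 227 ± 98.7 FPKM. Among the falls were Cd72, from 49.4 ± 0.64 to 3.62 ± 0.768 FPKM, Il21r, the interleukin-21 receptor, from 15.4 ± 8.4 to 0.818 ± 0.265 FPKM, and Plau, the urokinase plasminogen activator, from 69 ± 15.8 to 7.92 ± 2.25 FPKM. In all, 4562 genes passed (limma, Benjamini-Hochberg), 1753 higher and 2809 lower, and 647 of them changed by at least 1.

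Receptor targets rose in 12 of 22 cases and fell in 3 (12 and 4 adjusted over the list alone; camera adjusted p = 7.26e-06, and adjusted p = 0.0447 with an estimated correlation). FOXO targets rose in 13 of 27 cases and fell in 6 (15 and 6 adjusted over the list alone; camera adjusted p = 0.0148, and adjusted p = 0.18 with an estimated correlation). Irs2, an insulin receptor substrate on both of these lists, fell from 2.18 ± 0.519 to 1.19 ± 0.237 FPKM (limma adjusted p = 0.00374). Interferon-response genes fell in 26 of 29 cases, with an equal count adjusted over the list alone (camera adjusted p = 2.27e-12, and adjusted p = 0.0814 with an estimated correlation), and Ifit2 fell from 11.3 ± 1.35 to 1.22 ± 0.43 FPKM. Cholesterol synthesis genes fell in 19 of 20 cases, again with an equal count adjusted over the list alone (camera adjusted p = 7.26e-06, and adjusted p = 0.542 with an estimated correlation). Glycolysis and hypoxia genes fell in 12 of 22 cases and rose in 2 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0113, and adjusted p = 0.542 with an estimated correlation). Pkm, pyruvate kinase, fell by 1.12 ± 0.099 (SE, log2; limma adjusted p = 8.56e-07). Class II presentation genes fell in 8 of 10 cases, with an equal count adjusted over the list alone (camera adjusted p = 0.00503, and adjusted p = 0.542 with an estimated correlation). NF-kB inflammatory genes fell in 10 of 21 and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.00159, and adjusted p = 0.18 with an estimated correlation). The chemokine Ccl3 fell from 53.1 ± 14.7 to 15.9 ± 1.71 FPKM. Cell cycle genes fell in 17 of 29 (19 adjusted over the list alone; camera adjusted p = 2.52e-05, and adjusted p = 0.542 with an estimated correlation). Fc receptor, complement and phagocytic genes fell in 14 of 24 and rose in 4, as also adjusted over the list alone. That list did not pass (camera adjusted p = 0.0669), but passed as lower without the 3 libraries apart (camera adjusted p = 0.013). Macrophage markers fell in 6 of 10 cases and rose in 3, as also adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.55). Among the genes of cell-clearing macrophages 8 rose and 9 fell of 21, with equal counts adjusted over the list alone (camera adjusted p = 0.682). Their median was -0.59 and their mean -0.05, while the direction of the test was higher. Mertk rose from 26.6 ± 3.15 to 111 ± 7.09 FPKM. Stromal markers did not pass (camera adjusted p = 0.787), with a median of 0.06 and a mean of -0.13 (direction of the test higher). Median-ratio scaling gave 4597 calls, 48.4% of them higher against 38.4% with the deposited scaling, and quantile normalization gave 51.1% higher.

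The responses of both genotypes overlapped. Fkbp5, Tsc22d3, Jaml, Sult1a1, Ms4a4a, Cd72 and Mmp12 passed in the same direction in both, as did 2697 genes in all (980 higher, 1717 lower), and 4 genes passed in opposite directions. The latter count was 43 without wild-type dexamethasone replicate 4, 2 to 9 without each other library in turn, and 47 without the 3 libraries apart in Col1a1. Independent lists of these sizes would share 208.5 higher and 511.5 lower genes. The wild-type and knockout-labelled comparisons have no libraries in common. Across the 11654 genes the log2 differences had a Pearson r of 0.791 and a Spearman rho of 0.714; genes are not independent replicates, so no p is given. Among genes that also changed by at least 1, 384 were shared in direction, against 4.3 higher and 10.5 lower for independent lists.

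**Figure D3:**
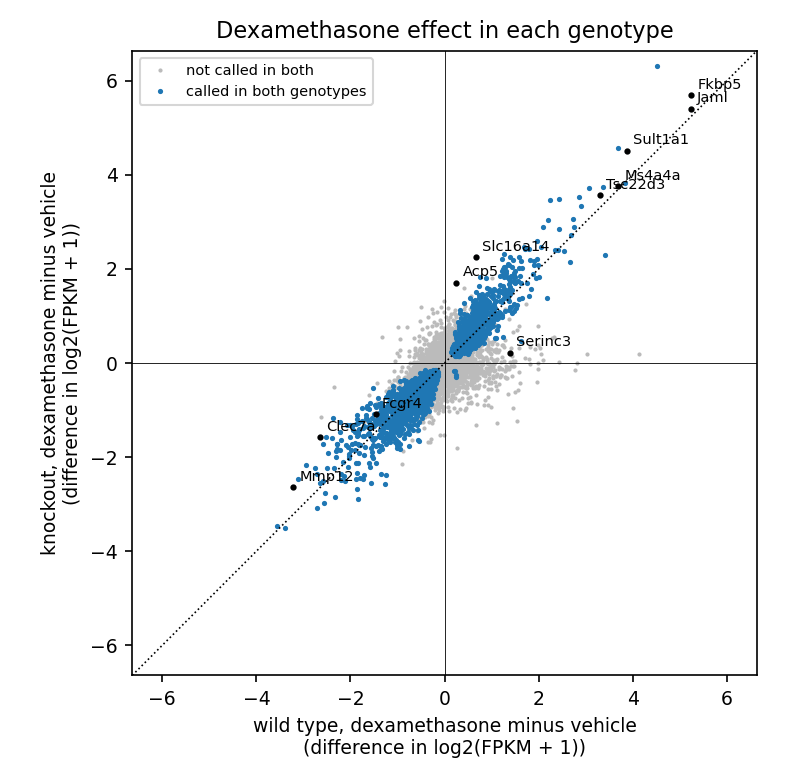
Difference in log2(FPKM + 1) between dexamethasone and vehicle in wild type (horizontal axis) and in knockout (vertical axis), 1 point per gene for 11654 genes; blue points passed in both genotypes and the dotted line marks equal differences. Fkbp5 lies at 5.24 and 5.70, and Serinc3 lies at 1.39 in wild type and 0.22 in knockout.

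Between the genotypes in vehicle, a small set of genes differed by large steps in every library. Angptl7, a secreted angiopoietin-like protein, stood at 0.351 ± 0.0733 to 15.7 ± 1.59 FPKM (SD, n = 4) from wild type to knockout, a difference of 3.62 ± 0.098 (SE, log2; limma, Benjamini-Hochberg adjusted p = 1.02e-11). Ndufs5, a subunit of respiratory complex I, measured 2.28 ± 0.319 to 41.1 ± 3.91 FPKM, while its near-copy BC002163, annotated as a processed pseudogene, went the other way, from 72.8 ± 6.09 to 2.15 ± 0.825 FPKM. BC002163 matches the Ndufs5 transcript at 317 of 319 bases, so reads of either gene can be counted at the other, and both values are uncertain. Slc40a1, the iron exporter ferroportin, was lower in the knockout-labelled libraries (29.8 ± 3.03 to 7.33 ± 1.74 FPKM), as was Npl, which breaks down sialic acid (33.7 ± 8.3 to 5.15 ± 1.11 FPKM). Lower values were also measured for Fblim1, a cytoskeletal linker (56.9 ± 5.93 to 12.1 ± 2.52 FPKM), and for Acp5, tartrate-resistant acid phosphatase (24.7 ± 2.86 to 5.42 ± 1.49 FPKM). Cd72 was higher (19.5 ± 4.57 to 49.4 ± 0.64 FPKM), as was Siglece, a sialic acid-binding receptor (2.65 ± 0.502 to 13.1 ± 3.34 FPKM). Adgre1 measured 615 ± 118 to 1282 ± 148 FPKM and passed as higher (limma adjusted p = 0.0101). Macrophage markers were higher in 1 of 10 cases (3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.145).

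In all, 545 genes passed in vehicle (limma, Benjamini-Hochberg), 393 higher and 152 lower in the knockout-labelled libraries. Of these, 43 were higher and 36 lower by at least 1. FOXO targets were lower in 7 of 27 cases and higher in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 1.14e-05, and adjusted p = 0.0412 with an estimated correlation). Irs2 was lower, at 4.69 ± 0.756 to 2.18 ± 0.519 FPKM, as were Mxi1, an antagonist of MYC (5.66 ± 0.222 to 3.1 ± 0.364 FPKM), and the mitochondrial kinase Pink1 (36.3 ± 4.02 to 24.7 ± 1.63 FPKM), with limma adjusted p of 0.00121, 0.000253 and 0.00869. Cdkn1b was lower too (10.1 ± 0.578 to 7.47 ± 1.07 FPKM; limma adjusted p = 0.0114) and lost its call with the stromal score as a covariate (limma adjusted p = 0.0562), at -0.39 ± 0.08 (log2, SE) without it and -0.35 ± 0.095 with it. Sesn1, also a FOXO target, lies close to Foxo3 on chromosome 10, at 41809935 to 41908424. It was higher, at 64.7 ± 12.9 to 91.3 ± 10.9 FPKM (limma adjusted p = 0.0212). With that covariate it lost its call (limma adjusted p = 0.124), at 0.50 ± 0.11 without the covariate and 0.34 ± 0.11 with it. Its call also ended when wild-type vehicle replicate 1, 2 or 4 or knockout-labelled vehicle replicate 1 or 3 was left out (limma adjusted p = 0.0794, 0.077, 0.076, 0.0706 and 0.0675), with log2 differences of 0.43 to 0.49. Interferon-response genes were higher in 6 of 29 cases (14 adjusted over the list alone; camera adjusted p = 2.16e-06, and adjusted p = 0.324 with an estimated correlation), including the RNA sensor Ddx58, at 9.87 ± 1.04 to 15.1 ± 2.36 FPKM. In the cholesterol synthesis list 1 of 20 genes passed as higher over all genes and 16 adjusted over the list alone (camera adjusted p = 4.16e-07, and adjusted p = 0.512 with an estimated correlation). Stromal markers were lower as a list (camera adjusted p = 1.99e-05, and adjusted p = 0.512 with an estimated correlation), although 0 of 10 passed by limma, overall or adjusted over the list alone, and 7 were lower at an unadjusted p under 0.05. Neither Col1a1 nor Col3a1 passed (limma adjusted p = 0.176 and 0.148). With the stromal score as a covariate the FOXO targets stayed lower (camera adjusted p = 2.03e-05, adjusted p = 0.0598 with an estimated correlation). The interferon and cholesterol lists stayed higher by camera (adjusted p = 3.84e-06 and 0.00381) and did not pass with an estimated correlation (adjusted p = 0.363 and 0.604). With that covariate 390 genes passed, 204 higher and 186 lower. The count of 545 rose to 1623 without wild-type vehicle replicate 3, to 1285 without knockout-labelled vehicle replicate 4, and to 3958 without these and wild-type dexamethasone replicate 4. It fell to 278, 286 and 303 without wild-type vehicle replicates 1, 2 and 4 in turn, and to 333, 347 and 291 without knockout-labelled vehicle replicates 1, 2 and 3. At a difference of at least 1, 61 were higher and 246 lower without wild-type vehicle replicate 3. Without knockout-labelled vehicle replicate 4 these were 54 and 169, and without all 3 libraries 100 and 652. Median-ratio scaling gave 485 calls, 60.4% of them higher against 72.1% with the deposited scaling, and quantile normalization gave 61.6% higher.

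Between the genotypes under dexamethasone, Cxcl12, 1 of the 10 stromal markers, was far lower in the knockout-labelled libraries. Gclc, an antioxidant gene, and Irs2, a FOXO target, were lower, and Irf7 and the Fc receptor gene Fcgr4 were higher. Cxcl12, a chemokine made by stromal cells, measured 133 ± 101 to 0.0961 ± 0.0935 FPKM (SD, n = 4) from wild type to knockout, a difference of -6.30 ± 1.16 (SE, log2; limma, Benjamini-Hochberg adjusted p = 0.00224). Serping1, the C1 inhibitor, measured 164 ± 124 to 0.766 ± 0.759 FPKM, Dpep1, a membrane dipeptidase, 156 ± 116 to 1.17 ± 1.09 FPKM, and Ogn, an extracellular matrix proteoglycan, 37.2 ± 22.5 to 0.374 ± 0.436 FPKM. In wild-type dexamethasone replicate 4, low in Col1a1, these genes were lowest of their group, at 12.2, 13.6, 14.7 and 4.5 FPKM. In knockout-labelled vehicle replicate 4, high in Col1a1, they measured 33.9, 46.9, 7.14 and 12.8 FPKM. Knockout-labelled dexamethasone replicate 4 held Cxcl12 at 0.197 FPKM with Col1a1 at 25.5 FPKM. Genotype and stromal content were not separated for these genes. Of 10 stromal markers 8 were lower (9 adjusted over the list alone; camera adjusted p = 0.000145, and adjusted p = 0.412 with an estimated correlation). Serinc3, a transmembrane protein, was lower at 627 ± 76.2 to 140.3 ± 6.04 FPKM (-2.15 ± 0.087; limma adjusted p = 1.21e-09). Angptl7 (0.181 ± 0.154 to 15.1 ± 1.44 FPKM) and Ndufs5 (2.27 ± 0.588 to 34.5 ± 1.93 FPKM) were higher, as in vehicle, and BC002163 was lower (67.4 ± 6.17 to 1.8 ± 0.716 FPKM). Ms4a4c, a relative of Ms4a4a, was higher at 1.76 ± 0.926 to 11.9 ± 1.54 FPKM.

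In all, 3114 genes passed under dexamethasone (limma, Benjamini-Hochberg), 1672 higher and 1442 lower, and of the 582 that differed by at least 1, 87 were higher and 495 lower. FOXO targets were lower in 12 of 27 cases and higher in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 2.05e-05, and adjusted p = 0.0492 with an estimated correlation). Irs2 measured 6.02 ± 0.327 to 1.19 ± 0.237 FPKM, Mxi1 9.22 ± 0.82 to 4.23 ± 0.561 FPKM, and Gabarapl1, an autophagy protein, 103 ± 8.48 to 51.7 ± 2.22 FPKM. Antioxidant genes were lower in 11 of 20 cases and higher in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 5.33e-06, and adjusted p = 0.348 with an estimated correlation). Gclc, the catalytic subunit for glutathione synthesis, measured 17.7 ± 1.83 to 9.39 ± 0.405 FPKM, and Gsr, glutathione reductase, 42.6 ± 6 to 21 ± 2.16 FPKM. Txnrd1, thioredoxin reductase, measured 33.2 ± 2.1 to 20.9 ± 1.45 FPKM, and Hmox1, haem oxygenase 1, 821 ± 62.3 to 556 ± 65.3 FPKM. Interferon-response genes were higher in 17 of 29 cases (20 adjusted over the list alone; camera adjusted p = 3.98e-06, and adjusted p = 0.348 with an estimated correlation), Irf7 among them at 4.7 ± 1.42 to 13.8 ± 3.25 FPKM. Fc receptor, complement and phagocytic genes were higher in 13 of 24 cases (16 adjusted over the list alone; camera adjusted p = 8.74e-05, and adjusted p = 0.348 with an estimated correlation). They included Fcgr4 at 12.9 ± 1.92 to 26.9 ± 3.17 FPKM. Amino acid and unfolded protein stress genes were lower in 6 of 17 cases (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000432, and adjusted p = 0.348 with an estimated correlation). Atf4 measured 43.7 ± 2.5 to 27.9 ± 1.36 FPKM. Glycolysis and hypoxia genes were lower in 8 of 22 cases and higher in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00184, and adjusted p = 0.396 with an estimated correlation). Macrophage markers were higher in 6 of 10 cases, with an equal count adjusted over the list alone (camera adjusted p = 0.007, and adjusted p = 0.396 with an estimated correlation), Adgre1 at 279.7 ± 128 to 705 ± 60.7 FPKM. Of the receptor targets 7 were lower and 2 higher of 22 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0239, and adjusted p = 0.348 with an estimated correlation). Fkbp5 was higher, at 81.6 ± 7.28 to 104 ± 7.46 FPKM, and lost its call with the stromal score as a covariate (limma adjusted p = 0.0712), at 0.36 ± 0.076 (log2, SE) without it and 0.32 ± 0.10 with it.

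With that covariate 941 genes passed under dexamethasone in place of 3114, 451 higher and 490 lower, and 67 were higher and 78 lower by at least 1. Lower genes also outnumbered higher ones with median-ratio scaling (1684 against 1502), with no filter on low values (1319 against 1293) and among libraries under 50 FPKM of Col1a1 (261 against 129). The FOXO and antioxidant lists then stayed lower (camera adjusted p = 2.64e-06 and 1.08e-14; adjusted p = 0.0218 and 0.0218 with an estimated correlation). The interferon and Fc lists stayed higher by camera (adjusted p = 1.34e-07 and 0.0021) and did not pass with an estimated correlation (adjusted p = 0.188 and 0.426). The stress, glycolysis and receptor target lists no longer passed (camera adjusted p = 0.208, 0.0642 and 0.153). The Col1a1 and Col3a1 calls ended, at log2 differences of 0.28 and 0.10 with the covariate against -4.33 and -4.20 without it. Both genes are part of the stromal score, so this end followed from how the covariate was built. Both calls were also lost without any 1 of wild-type dexamethasone replicates 1 to 3 and knockout-labelled dexamethasone replicates 1 to 3 (limma adjusted p of 0.0512 to 0.11 for Col1a1 and of 0.0507 to 0.0931 for Col3a1). The count of 3114 fell to 1517, 1600, 1708 and 1815 without wild-type dexamethasone replicates 1 and 3 and knockout-labelled dexamethasone replicates 1 and 2 in turn. The 582 genes that differed by at least 1 became 219, 382 and 218 without wild-type dexamethasone replicates 1, 2 and 3. They became 283 and 308 without knockout-labelled dexamethasone replicates 1 and 2. Among them 64, 91, 63, 74 and 81 were higher and 155, 291, 155, 209 and 227 lower. Without wild-type dexamethasone replicate 4 the 582 rose to 871, with 147 higher and 724 lower. In place of 87 higher and 495 lower, a pseudocount of 0.1 gave 194 and 550, and limma voom gave 196 and 279.

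**Figure D4:**
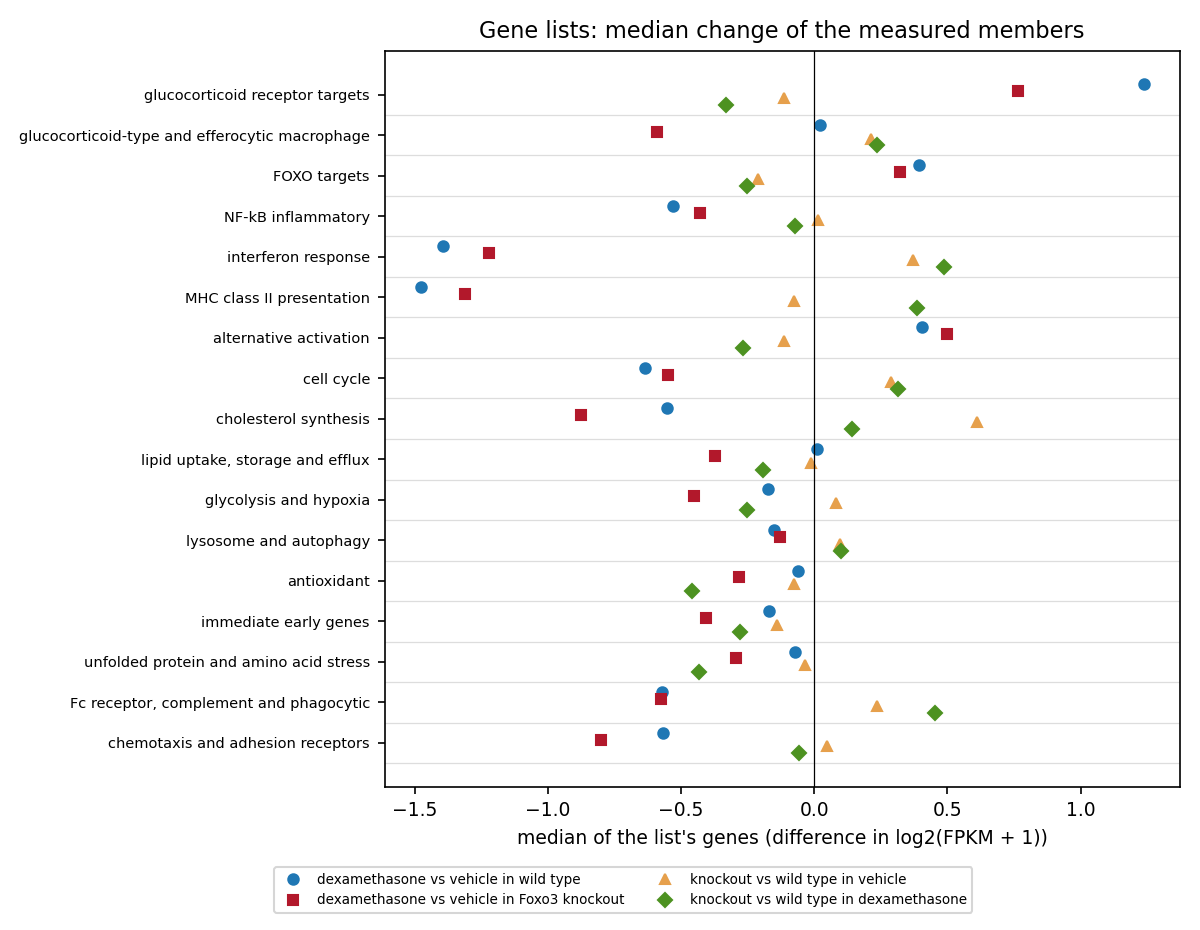
Median difference in log2(FPKM + 1) over the measured members of 17 gene lists, for dexamethasone against vehicle in wild type (circles) and knockout (squares) and for knockout against wild type in vehicle (triangles) and dexamethasone (diamonds). Interferon-response genes lie at -1.39 and -1.22 for dexamethasone and at 0.37 and 0.49 for genotype.

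The test of whether the dexamethasone response differed between genotypes passed 15 genes, 7 with a higher and 8 with a lower response in the knockout-labelled cells (limma, Benjamini-Hochberg). Serinc3 rose from 238 ± 23.7 to 627 ± 76.2 FPKM (SD, n = 4) in wild type. It stood at 120.2 ± 5.55 to 140.3 ± 6.04 FPKM in knockout-labelled libraries, a difference between responses of -1.17 ± 0.12 (SE, log2; adjusted p = 0.00157). Acp5 rose from 5.42 ± 1.49 to 19.5 ± 1.45 FPKM in knockout-labelled libraries and stood at 24.7 ± 2.86 to 29.9 ± 6.39 FPKM in wild type (1.46 ± 0.24; adjusted p = 0.0394). Slc16a14, of the monocarboxylate transporter family, rose in both, to 0.902 FPKM in wild type and 4.79 FPKM in knockout-labelled cells (1.59 ± 0.24); the wild-type rise missed the threshold after quantile normalization (limma adjusted p = 0.0562). Clec7a, the beta-glucan receptor dectin-1, fell further in wild type, from 27.2 ± 4.26 to 3.49 ± 0.554 FPKM, than in knockout-labelled cells, from 18.6 ± 2.65 to 5.61 ± 0.742 FPKM (1.08 ± 0.18). Fam126a, Galnt1 and Calml4 rose in both and by more in knockout-labelled cells, and Igbp1 rose in knockout-labelled cells, with differences between responses of 0.57 ± 0.072, 0.63 ± 0.095, 1.08 ± 0.19 and 0.41 ± 0.072. Tgfbr2, a receptor of transforming growth factor beta, Slc11a2, an iron transporter, Tef, a clock-output transcription factor, and Atf4 fell further in knockout-labelled cells, by differences of -0.63 ± 0.10, -0.68 ± 0.12, -0.59 ± 0.10 and -0.47 ± 0.078. The wild-type fall of Atf4 missed the threshold after quantile normalization (limma adjusted p = 0.0703). Bcl2l1, which encodes the survival factor BCL-XL, and Tspan4 fell in knockout-labelled libraries, from 37.8 ± 5.69 to 21.1 ± 1.77 FPKM and from 62.8 ± 3.43 to 30.9 ± 4.07 FPKM (-0.85 ± 0.14 and -0.81 ± 0.14). Rab15 rose in both, and by less in knockout-labelled cells (-1.14 ± 0.18), where it lay between 0.0755 and 0.742 FPKM. The receptor targets Fkbp5, Tsc22d3, Per1, Klf9 and Zbtb16 gave differences of 0.46 ± 0.11, 0.28 ± 0.27, -0.16 ± 0.16, -0.009 ± 0.18 and 0.036 ± 0.16, none of which passed. The list of receptor targets did not pass either (camera adjusted p = 0.484).

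Several lists differed in response with the preset correlation, and none of them with an estimated one. Few of their members passed singly. The direction of the test was lower in knockout-labelled cells for the FOXO target list (camera adjusted p = 0.031, and adjusted p = 0.649 with an estimated correlation), where 0 of 27 members passed by limma and 4 were lower adjusted over the list alone. This list no longer passed without the 3 libraries apart (camera adjusted p = 0.422). The direction was also lower for the lists of cholesterol synthesis (camera adjusted p = 5.73e-05, and adjusted p = 0.754 with an estimated correlation) and antioxidant genes (camera adjusted p = 9.56e-05, and adjusted p = 0.649 with an estimated correlation), with 0 of 20 and 0 of 20 members called, and 0 and 2 lower adjusted over the list alone. For glycolysis and hypoxia the direction was lower too (camera adjusted p = 0.000472, and adjusted p = 0.649 with an estimated correlation), with 0 of 22 called, and 1 higher and 1 lower adjusted over the list alone. Of 17 stress genes Atf4 alone passed, as lower, also adjusted over the list alone (camera adjusted p = 0.00221, and adjusted p = 0.649 with an estimated correlation). The direction was higher for class II presentation (camera adjusted p = 0.00489, and adjusted p = 0.692 with an estimated correlation), with 0 of 10 called, also adjusted over the list alone. Of 24 Fc receptor, complement and phagocytic genes Clec7a alone passed, as higher, also adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.655 with an estimated correlation). At an unadjusted limma p under 0.05, 6 FOXO target, 5 cholesterol, 8 antioxidant and 8 glycolysis genes were lower, and 1 antioxidant, 1 glycolysis and 2 class II genes were higher. Leaving out any library except wild-type vehicle replicate 3 moved the count of 15 by over 1.5 times, to 330 without wild-type dexamethasone replicate 4, to 32 without knockout-labelled vehicle replicate 4 and to between 2 and 7 otherwise. Serinc3 and Fam126a passed without each library in turn, while each of the other 13 lost its call without 8 to 15 of the 16 libraries (limma adjusted p of up to 0.123). Median-ratio scaling gave 17 calls, 58.8% of them with a higher response against 46.7% with the deposited scaling. A pseudocount of 0.1 gave 11 calls, 4 with a higher and 7 with a lower response, and 10 of them were among the 15. Of 100 splits, the real one among them, 12 gave as many calls, so chance is not excluded for the count.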

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

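The tests of stromal content, exchanged libraries, a segment near Foxo3, near-copies and Xist were chosen only after the result was seen, as were the counts over other splits of the libraries; the test of haplotypes was set before its result was seen. Single libraries standing apart from the other 3 of their group were looked for in 420 groups of named values by Dixon's ratio of gap to range, at its 95% critical value for 4 libraries. There were 39, where chance gives about 21. Of these, 18 lay in knockout-labelled vehicle replicate 4, 5 in wild-type dexamethasone replicate 4 and 4 in wild-type vehicle replicate 3.

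In knockout-labelled vehicle replicate 4, stromal and matrix genes stood above the other 3 libraries: Col1a1 at 95.8 FPKM, Col3a1 at 86.2, Lox at 55.2, Serping1 at 46.9, Cxcl12 at 33.9, Ogn at 12.8, Sned1 at 10.2, Dpep1 at 7.14 and Ptx3 at 5.23 FPKM. Il21r at 28 FPKM and Tgfbr2 at 84 FPKM were also high there. Ighv7-1 stood at 0.285 FPKM there against 0 in the others of its group, a value near the floor. Tsc22d3 at 16.3 FPKM, Pcp4l1 at 34.5, Hmox1 at 194.8, Tm4sf19 at 19.4, Bcl2a1d at 10.4 and Ms4a4c at 4.05 FPKM were low there. Wild-type dexamethasone replicate 4 was high in Tsc22d3 at 308.4 FPKM, Per1 at 52.2, Mertk at 137.2, Marco at 15.7 and Adgre1 at 471.7 FPKM. Wild-type vehicle replicate 3 was low in the stromal marker score at 1.76 and in Angptl7 at 0.242 FPKM, and high in Jaml at 0.428 and Sesn1 at 84.1 FPKM.

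In the other libraries, Cd74 at 841.8 FPKM and Ciita at 3.78 FPKM were high in wild-type vehicle replicate 4. Ciita was low at 1.35 FPKM and Adgre1 high at 1503 FPKM in knockout-labelled vehicle replicate 3. In knockout-labelled vehicle replicate 2, Fkbp5 was high at 1.16 FPKM and Angptl7 low at 13.3 FPKM. Among knockout-labelled dexamethasone libraries, Sult1a1 was high at 223.1 FPKM in replicate 1, Foxo4 low at 12.2 FPKM in replicate 2 and Jaml low at 35.8 FPKM in replicate 4. Among wild-type dexamethasone libraries, Fam126a was high at 6.99 FPKM in replicate 1, Plau low at 6.72 FPKM in replicate 2 and Pik3r1 low at 16.5 FPKM in replicate 3.

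The response to dexamethasone differed between genotypes by the interaction test in 15 genes. On the log2 scale, knockout minus wild type, the differences were -1.17 for Serinc3, -1.14 for Rab15, -0.85 for Bcl2l1, -0.81 for Tspan4, -0.68 for Slc11a2, -0.63 for Tgfbr2, -0.59 for Tef and -0.47 for Atf4. They were 1.59 for Slc16a14, 1.46 for Acp5, 1.08 for Calml4, 1.08 for Clec7a, 0.63 for Galnt1, 0.57 for Fam126a and 0.41 for Igbp1. By camera the responses also differed for cholesterol synthesis (camera adjusted p = 5.73e-05), antioxidant (9.56e-05), glycolysis and hypoxia (0.000472), Fc receptor (0.0012), stress (0.00221), class II (0.00489) and FOXO target genes (0.031). With an estimated correlation the adjusted p of these lists were 0.754, 0.649, 0.649, 0.655, 0.649, 0.692 and 0.649.

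With dexamethasone in wild type the real split gave 3508 genes and the highest of the other 34 gave 2. Only the real split was as large (1 of 35), the fewest this test allows. The same held in knockout (4562 against 2, 1 of 35) and for genotype under dexamethasone (3114 against 205, 1 of 35). In the latter the genotypes also differ in stromal markers, and 941 genes passed with the stromal score as a covariate. The splits cannot tell genotype and stromal content apart. Chance was not excluded for genotype in vehicle, where 2 of 35 splits gave as many. The split that put wild-type vehicle replicates 1, 2 and 4 with knockout-labelled vehicle replicate 4 gave 3254 genes against the real 545; these are the 4 vehicle libraries with Col1a1 above 50 FPKM, so this points to a structure of the samples other than the labels. For the interaction 12 of 100 splits, the real one included, gave 15 or more, the highest 1477.

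Fibroblast and stromal genes were lower in the knockout-labelled libraries, with 1 library apart from its group in each of 3 groups. An exchange of libraries between the genotypes was tested on 283 genes that separate the genotypes in the other 13 libraries. They placed wild-type vehicle replicate 3, wild-type dexamethasone replicate 4 and knockout-labelled vehicle replicate 4 with the opposite genotype in 94.8% of cases. All but 12 of those genes follow the stromal score by which the libraries were noticed, so this share decides nothing. In each of these libraries 0 of the 12 were placed with the opposite genotype. A gene that changed sides there would tend to follow the score, so this was partly fixed by how the 12 were chosen. By label, 10 genes separate all 16 libraries with a gap of at least 1 on the log2 scale, where the highest of 1000 random splits gave 5. These random splits kept groups of equal size, which exchanging these 3 libraries would not. The exchanged grouping was thus not among them. The 10 genes go against an exchange only as far as genotype sets their levels. Different amounts of stromal cells are consistent with 87.7% of 487 genes lower by 1 or more under dexamethasone following the stromal score within groups (correlation above 0.7), against 11.1% of 11644 genes; the score's own 10 genes were left out of both. Whether loss of Foxo3 alters how many stromal cells stay in the culture was not tested and stays open.

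The 10 genes that separate the genotypes in all 16 libraries lie on 6 chromosomes: Ndufs5, Angptl7, Gm11585 and AI506816 are higher in the knockout-labelled libraries, and Nab1, Npl, Zfp984, Gm5898, Gm7879 and BC002163 are lower. A segment around Foxo3 carried along with the knockout allele is argued against for these 10 genes. Of them 0% lie on chromosome 10 within 20 Mb of Foxo3, against 1% of all genes. It is not argued against for other genes. Sesn1 lies there, at 41809935 to 41908424, and passed as higher in knockout-labelled libraries in both treatments (limma adjusted p = 0.0212 and 0.0113). Both calls ended with the stromal score as a covariate (limma adjusted p = 0.124 and 0.267). Different haplotypes elsewhere in the genome cannot be told apart from chance for the 10 genes. Of them 20% lie within 1 Mb of another, which equals the 95th percentile of 10000 random sets, and 10 genes are few. For Ndufs5 and its near-copy BC002163, a candidate explanation is a sequence difference that moves reads between them: Ndufs5 was higher by 4.01 and BC002163 lower, at -5.17, while their summed reads differed by 0.412 on the log2 scale. An effect of Foxo3 loss on the rest of the 10 genes stays open and was not tested. Outside them, Rps3a3, a near-copy of Rps3a1, varied within groups. By replicate it measured 0.657, 178.1, 203 and 110.8 FPKM in knockout-labelled vehicle libraries. Under dexamethasone it measured 226.6, 213.5, 112.2 and 5.07 FPKM, and at most 1.02 FPKM in wild type. The cause was not tested. Fam126a, named for its response, lies close to AI506816 on chromosome 5 (from 23915276 and 23698296), so a haplotype there was not told apart from Foxo3 loss.

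Xist, which silences an X chromosome in female cells, stood at 0.981 FPKM in knockout-labelled vehicle replicate 4 and at 20.6 to 42.1 FPKM in the other 15 libraries; it was chosen after its values were seen. Cells of a male animal are argued against by 0 reads on the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in this library. A single active X chromosome would go with 5 of 7 genes known to escape X inactivation being lowest there among the 8 vehicle libraries (exact binomial p = 0.000515). That test takes the genes as independent, but all come from 1 library, which holds 18 of the 39 values standing apart from their group. Its p therefore overstates the support, and the question stays open. No biological explanation from the design was tested.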

How the results depend on the processing

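The stromal covariate, the removal of libraries apart in Col1a1, the limit on Col1a1 and limma voom were chosen only after the data were seen; the other settings were planned. Calls for dexamethasone lay within 1.5 times of 3508 and 4562 under every setting except for wild type among libraries with Col1a1 under 50 FPKM (2155). For genotype in vehicle, 545 calls became 244 with only 2 groups in the fit, 4840 with arrayWeights, 3958 without the 3 libraries apart and 60 (29 higher, 31 lower) with Col1a1 under 50 FPKM. Under dexamethasone, 3114 became 6388 with arrayWeights, 941 with the stromal covariate, 5158 without the 3 libraries and 390 with Col1a1 under 50 FPKM. The interaction's 15 became 6 with no filter, 1391 with arrayWeights, 134 with the stromal covariate, 725 without the 3 libraries, 1 with Col1a1 under 50 FPKM and 4 with limma voom. At a change of at least 1, a pseudocount of 0.1 and limma voom gave 787 and 816 calls in place of 511, 988 and 995 in place of 647, 131 and 127 in place of 79, and 744 and 475 in place of 582. For genotype that 79 also became 652 with arrayWeights and 39 with Col1a1 under 50 FPKM, and that 582 became 938 with arrayWeights, 308 with a filter of 5 FPKM, 890 without the 3 libraries and 95 with Col1a1 under 50 FPKM. The low counts with Col1a1 under 50 FPKM come with 9 libraries, 2 of them wild type. With arrayWeights the lowest weights fell on the 3 libraries apart. They were 0.248 for wild-type vehicle replicate 3, 0.206 for wild-type dexamethasone replicate 4 and 0.3 for knockout-labelled vehicle replicate 4. The cause of the moves was otherwise not tested. With the replicate block, counts were 2836 and 3877 for dexamethasone, 142 and 944 for genotype (76 higher and 94 lower by at least 1 under dexamethasone) and 1, Serinc3, for the interaction; the numbers do not pair the libraries, since same-numbered libraries correlated between -0.685 and 0.732, and not every library matched its own number best. Leaving out 1 library gave 2898 to 3633 and 3761 to 4442 for dexamethasone, 278 to 1623 and 1517 to 4070 for genotype, 2 to 330 for the interaction and 2318 to 2763 for the overlap of 2697. The overlap at a change of at least 1 was 384. The difference in Foxo3 ranged from -1.53 to -0.385 FPKM in vehicle and from 0.71 to 1.88 FPKM under dexamethasone. Of 125 list tests, 44 passed; 6 passed with an estimated correlation, 49 with median-ratio scaling, 46 with a pseudocount of 0.1, 45 with the stromal covariate and 55 without the 3 libraries. With the stromal covariate 5 passed with an estimated correlation, not including receptor targets in knockout (adjusted p = 0.0591 with an estimated correlation). Of the 125, 27 turned direction with that covariate, most without a call in either fit; the 9 with one were (camera from limma, adjusted p), in vehicle, cell cycle (0.589), lysosome (0.00904) and fibroblast (0.968), and under dexamethasone, cell cycle (0.375), cholesterol (8.47e-05), lysosome (0.015), monocyte (0.000192), fibroblast (0.244) and ribosomal (0.213). With that covariate and an estimated correlation none of these passed (adjusted p = 0.604 for lysosome in vehicle, and 0.426, 0.509 and 0.0517 for cholesterol, lysosome and monocyte under dexamethasone). Lists that passed only with another setting, besides those already given, were as follows (camera from limma, adjusted p). With the covariate they were, under dexamethasone, class II (0.00028), lipid handling (0.0425) and osteoclast (0.0218) between genotypes, Fc receptor (0.0418) and monocyte (0.0127) in knockout, and monocyte for the interaction (0.00217), none of which passed with an estimated correlation (adjusted p = 0.325, 0.426, 0.188, 0.534, 0.203 and 0.2). With a pseudocount of 0.1 they were class II and lipid handling between genotypes under dexamethasone (0.0451 each) and interferon for the interaction (0.00103). With median-ratio scaling they were stress (0.0486), Fc receptor (0.0467) and ribosomal genes (0.0467) between genotypes in vehicle, Fc receptor in knockout (0.0415) and macrophage markers for the interaction (0.0482). Without the 3 libraries they were stress (0.0358), Fc receptor (0.0329) and ribosomal genes (0.00193) in vehicle, and macrophage (0.000194) and monocyte markers (0.000725) for the interaction. Col3a1 with dexamethasone in wild type turned to -0.89, and for genotype under dexamethasone Col1a1 turned to 0.275 and Col3a1 to 0.102; the covariate is built from stromal genes, which shows the cause for these. Depth of 32.9 to 39.7 reads per FPKM at 2 kb limits what can be said of genes under 1 FPKM.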

Other observations

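The tests on the iron-handling and clock lists were chosen only after the results were seen; the other lists were fixed before. Chemotaxis and adhesion receptor genes fell with dexamethasone in 11 of 22 cases in wild type and rose in 2, with equal counts adjusted over the list alone (camera adjusted p = 0.0127, and adjusted p = 0.0609 with an estimated correlation). In knockout-labelled cells 12 fell and 3 rose (16 and 4 adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.0973 with an estimated correlation). Osteoclast markers were lower in knockout-labelled vehicle libraries (camera adjusted p = 0.0474, and adjusted p = 0.324 with an estimated correlation), with 1 of 5 called, a count that was equal adjusted over the list alone. This ended with a pseudocount of 0.1 (camera adjusted p = 0.057) and without the 3 libraries apart in Col1a1 (0.405). Receptor targets were lower in vehicle as a list (camera adjusted p = 0.0166, and adjusted p = 0.324 with an estimated correlation), with 1 of 22 called lower, also adjusted over the list alone, and this ended with the stromal covariate (camera adjusted p = 0.321). Antioxidant genes were lower there as a list (camera adjusted p = 0.0166, and adjusted p = 0.693 with an estimated correlation), with 1 of 20 called, also adjusted over the list alone, and this ended without those 3 libraries (camera adjusted p = 0.696). Cell cycle genes were higher as a list in vehicle (camera adjusted p = 0.0201, and adjusted p = 0.787 with an estimated correlation) and under dexamethasone (camera adjusted p = 0.0355, and adjusted p = 0.742 with an estimated correlation), with medians of 0.29 and 0.31. Of 29 members 1 was called higher and 1 lower in each (2 and 1 in vehicle and 1 and 1 under dexamethasone adjusted over the list alone). With the stromal covariate both turned lower and did not pass (camera adjusted p = 0.589 and 0.375). Ribosomal protein genes were lower as a list under dexamethasone (camera adjusted p = 0.0355, and adjusted p = 0.723 with an estimated correlation), with a median of -0.17. Of 20 members 2 were called lower by limma and 0 adjusted over the list alone, with 5 lower and 2 higher at an unadjusted p under 0.05. With the covariate the list turned higher and did not pass (camera adjusted p = 0.213).

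With dexamethasone, the lists on alternative activation (0.342 in wild type and 0.262 in knockout, camera adjusted p from limma), lipid handling (0.879 and 0.4), lysosome and autophagy (0.364 and 0.294) and immediate early genes (0.342 and 0.249) did not pass. For lipid handling in wild type the median was 0.009 and the mean -0.13 (direction of the test lower), and for alternative activation in knockout 0.50 and -0.01 (direction of the test higher). Neither did markers of neutrophils (0.339 and 0.189), monocytes (0.342 and 0.0641) and B cells (0.638 and 0.46), or mitochondrial transcripts (0.614 and 0.981). Between genotypes the same lists did not pass in vehicle or under dexamethasone; for lipid handling the camera adjusted p was 0.0928 and 0.0557 (0.0451 with a pseudocount of 0.1 and 0.0425 with the stromal covariate in the latter, both as lower), and for immediate early genes 0.06 and 0.0636. Without the 3 libraries apart in Col1a1 some of these lists passed by camera. In knockout with dexamethasone they were alternative activation (adjusted p = 0.0372), lysosome (0.0278) and monocyte genes (0.00597). Between genotypes in vehicle they were alternative activation (0.0393), immediate early (0.0177) and monocyte genes (0.00717), and under dexamethasone immediate early genes (0.0288).

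The clock genes Tef and Per1 led to the hypothesis that a list of 15 other measured clock genes moves with dexamethasone in both genotypes. It was not met: the camera adjusted p was 0.405 in wild type and 0.317 in knockout, and members went both ways, with Dbp, Bhlhe41 and Per3 lower and Arntl and Nfil3 higher in both. A difference not foreseen was that the list was lower in knockout-labelled than in wild-type libraries under dexamethasone. There 7 of 15 members were lower, or 10 adjusted over the list alone (camera adjusted p = 4.29e-05, and adjusted p = 0.00529 with an estimated correlation). Over all 10 tests of these lists the values were 0.000215 and adjusted p = 0.0265 with an estimated correlation. With the stromal score as a covariate the camera adjusted p was 0.000228, and adjusted p = 0.0233 with an estimated correlation. The response itself was lower as a list in the fit without that covariate (camera adjusted p = 0.000584, and adjusted p = 0.0148 with an estimated correlation). With the covariate these were 0.00246 and adjusted p = 0.0559 with an estimated correlation. Of the 15 members 0 passed in that test of the response over all genes by limma, 6 had an unadjusted p under 0.05, and 4 were lower adjusted over the list alone. In vehicle the list gave a camera adjusted p of 0.0386, but 0.0643 over all 10 tests of these lists, which did not pass. There the adjusted p was 0.12 with an estimated correlation, and the camera adjusted p was 0.296 with the covariate. This was noticed and tested on the same data, and the times of day at which cells were collected are not given in the sources used here.

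The iron genes Slc40a1 and Slc11a2 led to the hypothesis that 14 other measured iron-handling genes differ between the genotypes as a set. It was not met, with a camera adjusted p from limma of 0.737 in vehicle and 0.889 under dexamethasone.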
